A study of Homo sapiens with 13 samples.

How the data were processed

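RNA from SW480 cells, an established human colon cancer line, was measured on 13 Affymetrix Human Gene 1.0 ST arrays, which hold probes along the whole length of each transcript. Cells had been kept for 6 h in the solvent DMSO at 0.1 percent (n = 4), in DFO (n = 4), in Deferasirox (n = 3) or in OICR623 (n = 2). The series text describes the replicates as independent experiments. Doses were taken as the labels give them, 100 mM for DFO, 50 mM for Deferasirox and 10 mM for OICR623; these are high for cells in culture, and the labels hold nothing that settles whether another unit was meant. The labels give RNA amounts in a unit that is as improbable.

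The deposited values are log2 signals, 1 per transcript cluster and array, as their range shows. GCRMA and limma are named in the submitters' processing notes, without a version, an order or the step each served. The table holds 32321 transcript clusters. With the probe table, 19158 of them were named by 1 gene symbol, 1388 by several and 11775 by none, and 19128 were matched to the reference gene table (assembly GRCh38.p14, used for names only) by their Entrez identifier; 0 symbols had to be updated. Where a gene had more than 1 transcript cluster, as 637 genes did, the one with the highest mean over all arrays was kept, which left 18404 genes. No filter on dim genes was applied. The values carry no detection calls, so no signal could be set against a measured background, and the number of arrays limits the precision of every value.

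The medians of the 13 arrays fell into 3 levels, separated where neighbouring medians lay more than 0.05 apart. The high level (7.17 to 7.19) held DMSO 1 and DFO 1, and the low level (6.52 to 6.55) held DMSO 4, DFO 4 and Deferasirox 3. The other 8 arrays, among them both OICR623 arrays, made up the middle level (6.64 to 6.69). Correlations of 2 arrays of 1 level lay between 0.995 and 0.998, and those of 2 arrays of different levels between 0.980 and 0.994.

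Differences between groups were tested with limma 3.58.1 in R 4.3.3 (with statmod 1.5.0), with 1 mean per group over all 13 arrays and empirical Bayes moderation. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the comparison. This fit without a block, the gene lists and the naming rule were set before the data were examined. The 3 levels were seen afterwards, and a fit with the level as a block, its own alternatives and the genes named from it were chosen after the data had been seen; both fits are reported. Comparisons were made of each compound with DMSO and of each pair of compounds.

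Whether replicate numbers pair the arrays was checked on the correlation, across genes, of the deviations of same-numbered arrays from their group means. For DMSO and DFO it was 0.945, 0.662, 0.738 and 0.788 for numbers 1 to 4. These numbers were taken as pairs on that basis, since the labels state no pairing. A replicate block was therefore also fitted for DFO against DMSO, with all arrays and with the 8 arrays of these groups alone. The deviations hold the levels, however, and DMSO and DFO arrays of the same number lie in the same level. These correlations thus cannot tell a pairing from a shared level.

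For testing, 38 gene lists with 795 distinct members, of which 733 were measured, had been fixed: targets of hypoxia-inducible factor (HIF), glycolysis, 3 lists on iron and iron-dependent enzymes, Wnt targets and components, cell cycle and histone lists, stress responses, signalling, metabolism, ribosomes, and markers of intestinal epithelium, fibroblasts, endothelium and leukocytes. Each was tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and beside it with camera at an estimated correlation and with fry. Members were counted as higher, lower or not called over all genes and adjusted over the list alone. Intervals of list means came from the fit with the level as a block to the mean of each list.

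The genes named were fixed by rule. For each compound against DMSO they were the 8 highest and 8 lowest called genes whose arrays did not overlap with DMSO, 15 genes fixed by name (13 of them measured; FTH1 and CA9 were not) and up to 4 called members, by smallest adjusted p, of each list past its set test. Between compounds they were the 5 highest and 5 lowest called genes without overlap and the genes fixed by name. The same rule was applied to the fit with the level as a block. Genes outside it are said to have been named or chosen after their values were seen.

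Because the 3 compounds share the DMSO arrays, overlaps and correlations of their changes were set beside the overlap of independent lists, beside 100 simulations of unchanged groups against the same controls, and beside fits in which each compound had its own control arrays. The scripts were tested on simulated data, with 50 genes changed by each of 4 sizes among 18404. These data were drawn from the level-blocked fit, with its level shifts and independent noise at its residual spread. The test therefore favours the block by construction, and the shares recovered are no evidence for choosing it. For DFO, 60 percent of genes changed by 1 on the log2 scale were recovered without a block and 100 percent with the level as a block, which also made 14 false calls. For Deferasirox the shares at that size were 62 and 100 percent, and for OICR623 they were 36 and 98 percent. At a change of 0.5 without a block, 0 percent was recovered for DFO, 2 percent for Deferasirox and 0 percent for OICR623, against 94, 94 and 82 percent with the level as a block.

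Alternatives covered the filter on dim genes, quantile normalization, centring of arrays on their medians, all transcript clusters, the moderation setting, the arrays in the fit, array weights, the call threshold, the replicate block, the set test, the controls and each array left out. Added after the data had been seen were the level block, the middle level alone and the fit without both arrays of the high level. Transcript clusters without exactly 1 gene symbol stayed out of the comparisons of genes and were tested apart. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.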

Results

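The series asked how iron chelators change gene expression in SW480 colon cancer cells. DFO (deferoxamine) and Deferasirox are iron chelators in clinical use, and OICR623 is known here only by its code name. After 6 h of treatment, RNA was measured on 13 arrays, 4 of DMSO, 4 of DFO, 3 of Deferasirox and 2 of OICR623. The doses differed, with 100 mM DFO, 50 mM Deferasirox and 10 mM OICR623 as the labels give them, so no pair of compounds was compared at a matched dose. The median log2 signal of the arrays fell into 3 levels that did not follow the groups, and only the middle level held all 4 of them. Values are therefore given from the fit without a block, which was planned, and from the fit with the level as a block, which was chosen after the levels had been seen.

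**Figure D1:**
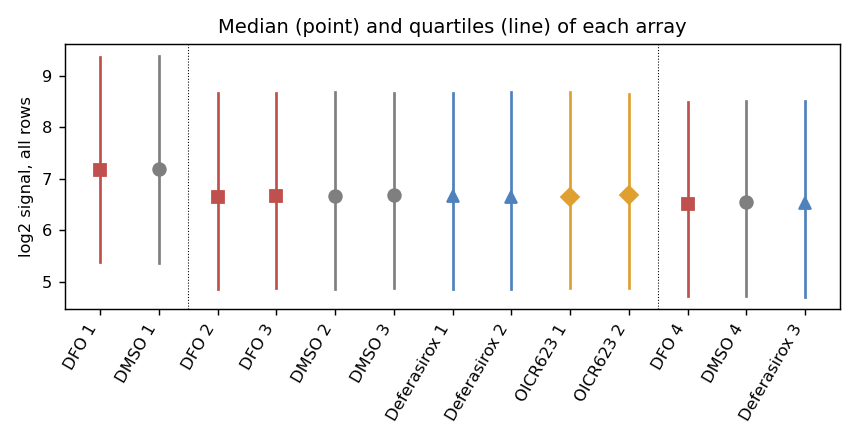
Median (point) and quartiles (line) of the log2 signal of each of the 13 arrays, with dotted lines between the 3 levels of the medians. DMSO 1 and DFO 1 lie at 7.17 to 7.19, 8 arrays at 6.64 to 6.69, and DMSO 4, DFO 4 and Deferasirox 3 at 6.52 to 6.55.

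Under DFO (n = 4, against DMSO with n = 4), DDIT4 rose most, by 3.08 on the log2 scale (SE 0.20), or 8.44-fold (transcript cluster 7928308). DDIT4 restrains mTOR signalling and is induced by low oxygen and stress. ARRDC3, an arrestin-domain protein, rose by 2.34 (SE 0.16), ADM, which encodes the vasodilator adrenomedullin, by 2.15 (SE 0.21), and EGLN3, a prolyl hydroxylase that acts on HIF, by 1.98 (SE 0.19). ERRFI1, a feedback inhibitor of the EGF receptor, rose by 1.96 (SE 0.18), IGFBP3 by 1.88 (SE 0.29), the sulfotransferase gene CHST15 by 1.74 (SE 0.15) and the angiogenic factor VEGFA by 1.69 (SE 0.24). The adjusted p values of these 8 genes lay between 6.1e-06 for DDIT4 and 0.0084 for IGFBP3. NDRG1, which responds to iron depletion and hypoxia in many cells, rose by 1.32 (SE 0.16).

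All 25 genes that fell under DFO without a block were histone genes. The linker histone gene H1-5 (transcript cluster 8124527) fell by 3.21 (SE 0.38, adjusted p = 0.0011) and H3C12 fell by 2.90 (SE 0.32). H2AC15 changed by -2.29 (SE 0.29), H2BC14 by -2.25 (SE 0.28), and H1-2, H2AC20, H3C11 and H3C7 by -2.24 to -2.15. Within the high, middle and low levels, the difference of DFO and DMSO was 2.73, 3.09 and 3.41 for DDIT4 and -2.98, -3.17 and -3.52 for H1-5.

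Without a block 45 of 18404 genes were called by limma, 20 higher and 25 lower, and with the level as a block 847 were, 347 higher and 500 lower. All 45 were also called with the level as a block and had the same sign in each of the 3 levels. With the replicate number as a block the count was 78 over all arrays and 619 over the 8 DFO and DMSO arrays alone, and without DMSO 1 and no block it was 81. The count with the level as a block was 494 without DFO 4 and 497 without DMSO 4. Among the DMSO arrays, DMSO 1 stood apart from the other 3 for EGLN3, H2AC20, PDK1, MOB3A and the HIF and ATF4 lists. Among the DFO arrays DFO 1 did so for ARRDC3, CHST15, H2AC20 and LGR5. DMSO 1 and DFO 1 are the only arrays of their groups in the high level, so a single array cannot be told from its level here.

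Of the 38 measured HIF target genes outside glycolysis, 9 rose, 0 fell and 29 were not called without a block (15 higher and 0 lower adjusted over the list alone). ANGPTL4, a regulator of lipid uptake, rose by 1.40 (SE 0.16) and the transcriptional repressor BHLHE40 by 1.59 (SE 0.19). With the level as a block 24 rose, 1 fell and 13 were not called (31 and 1 adjusted over the list alone), and the member that fell was BHLHE41, with a change of -0.27. BHLHE41 was named after its values were seen, here and for the other compounds. The list mean was 0.67 in both fits, as DFO and DMSO have the same number of arrays in each level. Its 95% interval with the block was 0.54 to 0.79. It lay at 0.46, 0.69 and 0.82 in the high, middle and low levels. The set test gave an adjusted p of 3.1e-86 without a block, and an adjusted p of 0.038 with an estimated correlation.

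Genes of glycolysis and glucose uptake rose as a list under DFO (mean 0.30, interval 0.22 to 0.37; adjusted p = 4.0e-22, and adjusted p = 0.40 with an estimated correlation). Of 24 measured members, PFKFB3 and PFKFB4, which make the activator of phosphofructokinase, were the 2 called without a block (5 adjusted over the list alone), at 1.04 (SE 0.16) and 0.95 (SE 0.17). Neither call held without DMSO 2. In the blocked fit 9 rose, 0 fell and 15 were not called (15 higher adjusted over the list alone), among them the glucose transporter genes SLC2A1 at 0.58 (SE 0.06) and SLC2A3 at 0.97 (SE 0.11). PDK1, a kinase gene whose product inhibits pyruvate dehydrogenase, changed by 0.56 and was called by limma only with the block (adjusted p = 7.2e-05). The list of iron- and oxoglutarate-dependent dioxygenases, enzymes that need iron to work, also rose, with a mean of 0.20 (interval 0.13 to 0.27). Its median was 0.03, so a few members carried the mean. The set test gave an adjusted p of 7.7e-08, and an adjusted p of 0.996 with an estimated correlation. Of its 29 members EGLN3 was the 1 called without a block (3 adjusted over the list alone). With the block 6 rose and 0 fell (9 adjusted over the list alone). Among them were the histone demethylase genes KDM3A at 1.22 (SE 0.08) and KDM7A at 0.53 (SE 0.07) and the collagen hydroxylase gene P4HA1 at 0.80 (SE 0.06). EGLN3, KDM3A and P4HA1 also belong to the HIF list, as do EGLN1, KDM4B, P4HA2 and PLOD2. The dioxygenase list is therefore no separate measure from the HIF list for any compound.

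Of the 30 measured replication-dependent histones, which are made mainly in S phase, 0 rose, 15 fell and 15 were not called under DFO without a block (28 lower adjusted over the list alone), and with the level as a block 29 fell. H2BC9 changed by -2.05 (SE 0.23) and H3C8 by -1.97 (SE 0.22). The list mean was -1.45 (interval -1.60 to -1.30), with an adjusted p of 2.6e-220 by the set test and an adjusted p of 0.0013 with an estimated correlation. Genes of the G1/S transition rose as a list with a mean of 0.22 (interval 0.16 to 0.27; adjusted p = 2.3e-11 without a block, and adjusted p = 0.996 with an estimated correlation). Of its 26 members 0 were called without a block, by the list alone as well, and 12 rose with it (21 adjusted over the list alone), led by the cyclin genes CCNE2 at 0.98 (SE 0.05) and CCNE1 at 0.75 (SE 0.06). The G2/M list fell, with a mean of -0.38 (interval -0.48 to -0.28; adjusted p = 1.0e-23, and adjusted p = 0.40 with an estimated correlation). Of its 26 members 0 were called without a block and 20 fell with it (25 adjusted over the list alone), such as the mitotic kinase genes PLK1 at -0.72 (SE 0.06), AURKA at -0.77 (SE 0.07) and BUB1B at -0.52 (SE 0.04).

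Wnt/beta-catenin target genes fell as a list, with a mean of -0.16 (interval -0.19 to -0.13), by the set test without a block (adjusted p = 5.1e-05, and adjusted p = 0.996 with an estimated correlation) and with it (adjusted p = 4.7e-05, and adjusted p = 0.029 with an estimated correlation). None of its 30 members was called without a block, whereas with it 9 fell, 1 rose and 20 were not called (12 lower and 1 higher adjusted over the list alone). BAMBI, a decoy receptor for TGF-beta signals, changed by -1.02 (SE 0.05), the transcription factor gene PROX1 by -0.63 (SE 0.05) and the growth factor gene FGF20 by -0.80 (SE 0.07), while SOX9 was the member that rose, by 0.22 (SE 0.04). MYC changed by -0.41 (block adjusted p = 0.0010) and LGR5, a stem cell receptor, by -0.34 (block adjusted p = 0.014). AXIN2 stood at -0.22 (block adjusted p = 0.056) and was called with the replicate number as a block on the 8 arrays alone (adjusted p = 0.038). NKD1 at -0.07 and CCND1 at 0.04 were not called in either fit.

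The list of iron uptake, storage and export did not pass the set test, with a mean of -0.01 (interval -0.06 to 0.03) over 25 members. In the blocked fit 2 rose (4 adjusted over the list alone), TFRC, the transferrin receptor gene, by 0.22 (SE 0.05, adjusted p = 0.018) and BMP6 by 0.16, and 2 fell (4 adjusted over the list alone), FBXL5 with -0.58 and STEAP2 with -0.31. Without a block none was called. BMP6, FBXL5 and STEAP2 were named after their values were seen. SLC11A2, an iron transporter gene, changed by 0.06 (block adjusted p = 0.72). The cell cycle inhibitor gene CDKN1A, at 0.39, and the stress gene DDIT3, at -0.33, passed only with the level as a block (adjusted p = 0.0014 and 0.030).

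The lists of ATF4 targets and of immediate early genes rose by the set test under DFO (means 0.15 and 0.15; adjusted p = 5.6e-04 and 1.2e-06, and adjusted p = 0.996 for both with an estimated correlation). Once the level was a block, 5 ATF4 targets rose and 2, DDIT3 and CTH, fell (6 and 2 adjusted over the list alone), while 10 immediate early genes rose and 1, MYC, fell (11 and 1 adjusted over the list alone). STC2 rose by 0.77 (SE 0.07) and the phosphatase gene DUSP1 by 0.78 (SE 0.08) in that fit. STC2, DDIT4 and VLDLR of the ATF4 list also belong to the HIF list, and DDIT4 was the gene that rose most under DFO. The rise of the ATF4 list is therefore not separate from that of the HIF targets. The ribosome biogenesis list fell, with a mean of -0.09 (interval -0.13 to -0.06; adjusted p = 0.0022, and adjusted p = 0.996 with an estimated correlation). Of its 27 members 4 fell with the level as a block, RRS1, POLR1B, DDX10 and POLR1C, by -0.31 to -0.19 (10 adjusted over the list alone). Altogether 10 of 38 lists passed without a block and 13 with the level as a block. Other splits of the DFO and DMSO arrays gave up to 13 lists without a block, more than the real one, and up to 11 with it.

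**Figure D2:**
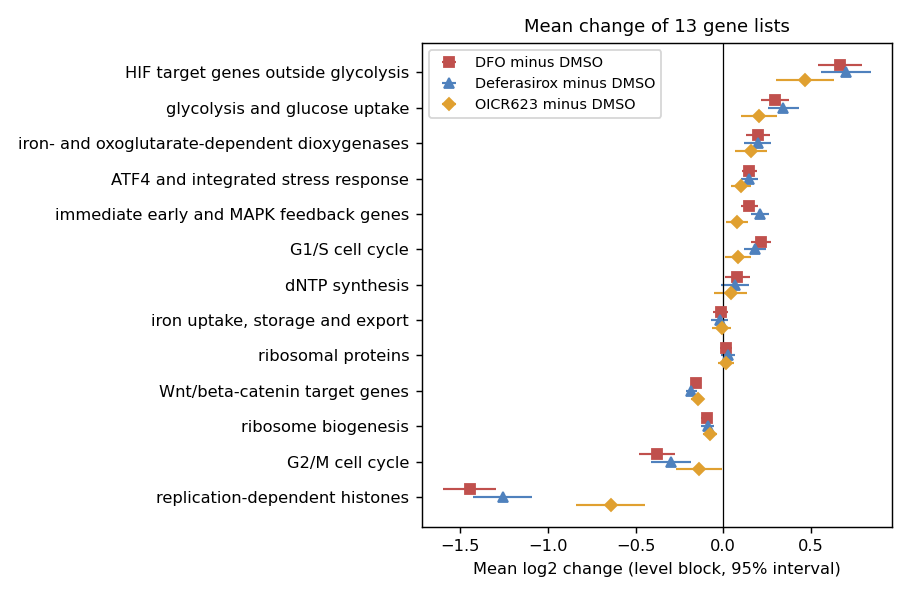
Mean log2 change of 13 gene lists against DMSO (x axis) for DFO, Deferasirox and OICR623 in the fit with the level as a block, with 95% intervals as lines. The histone list lies at -1.45, -1.26 and -0.64 and the HIF target list at 0.67, 0.70 and 0.47.

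Under Deferasirox (n = 3), the same 2 genes led the rises, DDIT4 at 2.89 (SE 0.21, adjusted p = 1.9e-05) and ARRDC3 at 2.47 (SE 0.17) without a block. The median of all genes was shifted by -0.15 in this fit and by 0.00 with the level as a block, where the values were 3.03 (SE 0.12) and 2.57 (SE 0.06). ERRFI1 rose by 2.21 (SE 0.11), ADM by 2.20 (SE 0.12), IGFBP3 by 2.08 (SE 0.22), CHST15 by 1.95 (SE 0.10), EGLN3 by 1.94 (SE 0.11), ANGPTL4 by 1.78 (SE 0.13) and VEGFA by 1.76 (SE 0.12) with the block, and all of these were called without it as well, as was NDRG1 at 1.39 (SE 0.18). The calls of VEGFA and IGFBP3 without a block were lost without any 1 of the Deferasirox arrays and without DMSO 2 or DMSO 3.

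Of the 25 genes that fell under Deferasirox without a block, 24 were histone genes and the other was NRP2, a receptor for semaphorins and VEGF, named after its values were seen. H1-5 changed by -3.32 (SE 0.41, adjusted p = 0.0021) and H3C12 by -2.89 (SE 0.35), and with the level as a block by -3.05 (SE 0.22) and -2.65 (SE 0.12). H3C1 changed by -2.08, H1-2 by -2.01, H2BC14 by -1.85, H3C2 by -1.84, H2AC20 by -1.82 and H3C10 by -1.74 in the fit with the block. The calls of H2AC20 and H3C10 without a block were lost without any 1 of the Deferasirox arrays.

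Without a block 43 genes were called by limma, 18 higher and 25 lower, and with the level as a block 1074 were, 521 higher and 553 lower. All 43 were also called with the block, with the same sign in each of the 2 levels that hold both groups. Without a block the count was 73 without DMSO 1, 25 without Deferasirox 1 and 22 without Deferasirox 3; with the block it was 589 without DMSO 4, 712 without Deferasirox 2 and 546 without Deferasirox 3.

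HIF targets outside glycolysis rose as a list under Deferasirox, with a mean of 0.70 with the block (interval 0.56 to 0.84) and 0.53 without it (adjusted p = 1.4e-75 without it, and adjusted p = 0.058 with an estimated correlation). Without a block 8 of 38 rose and 0 fell (13 adjusted over the list alone), and with the block 26 rose and 1, BHLHE41, fell (31 and 1 adjusted over the list alone). BHLHE40 rose by 1.67 (SE 0.06) and ANKRD37 by 0.93 (SE 0.06). The glycolysis list rose too (mean 0.34 with the block, interval 0.26 to 0.43; mean 0.20 without it, adjusted p = 2.1e-22, and adjusted p = 0.48 with an estimated correlation). None of its 24 members was called without a block (3 adjusted over the list alone) and 11 rose with it (17 adjusted over the list alone), among them the hexokinase gene HK2 at 0.58 (SE 0.07) and PDK1 at 0.66 (SE 0.06). Histones fell, with a list mean of -1.26 with the block (interval -1.43 to -1.09) and -1.48 without it (adjusted p = 9.2e-115, and adjusted p = 0.016 with an estimated correlation). Of 30 members 14 fell without a block (29 adjusted over the list alone) and 29 with it, such as H3C7 at -1.87 (SE 0.08) and H3C8 at -1.76 (SE 0.08).

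The list of the unfolded protein response, chaperones and degradation factors of the endoplasmic reticulum, rose under Deferasirox (mean 0.20 with the block, interval 0.14 to 0.26; mean 0.05 and median 0.00 without it, adjusted p = 1.0e-06, and adjusted p = 0.97 with an estimated correlation). Of 19 members 0 were called without a block and 5 rose with it (12 adjusted over the list alone), HERPUD1 at 0.75 (SE 0.06), DNAJB9 at 0.40 (SE 0.08), SEL1L at 0.34 (SE 0.06), EDEM1 at 0.31 (SE 0.06) and HSPA5 at 0.28 (SE 0.04). Immediate early genes rose as a list, with a mean of 0.21 with the block (interval 0.16 to 0.26) and 0.01 without it (median -0.01, adjusted p = 7.8e-08, and adjusted p = 0.97 with an estimated correlation). Of 27 members 12 rose with the block (15 adjusted over the list alone), among them JUN at 0.75 (SE 0.05) and DUSP6 at 0.50 (SE 0.06). G2/M genes fell (mean -0.30 with the block, interval -0.41 to -0.19; mean -0.54 without it, adjusted p = 3.5e-12, and adjusted p = 0.97 with an estimated correlation). In the fit with the block 17 were lower and 1, UBE2C, named after its values were seen, was higher (23 and 1 adjusted over the list alone). G1/S genes rose relative to all genes (block mean 0.18, interval 0.12 to 0.24; adjusted p = 5.8e-04 without a block, and adjusted p = 0.97 with an estimated correlation). Of 26 members 9 rose with the block, also adjusted over the list alone. Their mean without a block was -0.01, below 0 although the test was upward, because all genes had shifted down in that fit.

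Wnt/beta-catenin targets fell under Deferasirox (without a block mean -0.38, adjusted p = 7.6e-05, and adjusted p = 0.97 with an estimated correlation; with it mean -0.18, interval -0.21 to -0.15, adjusted p = 3.0e-06, and adjusted p = 0.015 with an estimated correlation). With the block 8 of 30 fell and 1, SOX9, rose (12 and 1 adjusted over the list alone), BAMBI at -1.10 (SE 0.06), LGR5 at -0.67 (SE 0.07, adjusted p = 3.4e-04) and AXIN2 at -0.25 (SE 0.06, adjusted p = 0.044) among them. None was called without a block. MYC, at -0.14, NKD1, at -0.09, and CCND1, at 0.08, were not called. TFRC stood at -0.01 without a block, where it was not called, and rose by 0.23 (SE 0.05, adjusted p = 0.023) with it. CDKN1A rose by 0.48 (SE 0.06) with the block, while SLC11A2 at -0.13 and DDIT3 at -0.06 were not called. The iron uptake list did not pass (block mean -0.02, interval -0.07 to 0.03), with 3 members higher and 2 lower in the blocked fit (4 and 4 adjusted over the list alone). The dioxygenase list rose relative to all genes (block mean 0.20, interval 0.12 to 0.27; adjusted p = 1.3e-04 without a block, where its mean was -0.01, and adjusted p = 0.97 with an estimated correlation). Its members numbered 6 higher and 0 lower in the blocked fit (7 higher and 1 lower adjusted over the list alone). In each fit 12 lists passed. Metallothioneins passed only without a block (adjusted p = 0.022, and adjusted p = 0.97 with an estimated correlation) and NF-kB targets only with it (adjusted p = 0.028, and adjusted p = 0.12 with an estimated correlation). Other splits of the arrays gave up to 14 lists without a block and up to 15 with it.

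OICR623 (n = 2) raised 7 genes and lowered 0 by limma without a block. ARRDC3 rose by 2.14 (SE 0.19, adjusted p = 5.7e-04), DDIT4 by 1.98 (SE 0.24), ERRFI1 by 1.68 (SE 0.21), EGLN3 by 1.63 (SE 0.24) and CHST15 by 1.51 (SE 0.19). The kinase gene HUNK rose by 1.21 (SE 0.19) and MOB3A, of the family of MOB kinase activators, by 1.07 (SE 0.16). The median of all genes was shifted by -0.11 in this fit. With the level as a block, where that shift was 0.00, these 7 genes rose by 2.20, 2.14, 1.77, 1.71, 1.52, 1.15 and 1.07. In that fit ADM also rose, by 1.78 (SE 0.14), BHLHE40 by 1.43 (SE 0.07), NDRG1 by 1.21 (SE 0.09) and VEGFA by 1.02 (SE 0.14), and H3C12 changed by -1.70 (SE 0.14), H1-5 by -1.35 (SE 0.26), H2AC15 by -1.29 (SE 0.16) and H3C1 by -1.28 (SE 0.13).

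The fit with the level as a block called 135 genes, 62 higher and 73 lower; 104 genes had an unadjusted p under 0.05 without a block. Both OICR623 arrays lie in the middle level, which holds 2 of the 4 DMSO arrays. Without a block the count was 1 without either OICR623 array, 4 without DMSO 2, DMSO 3 or DMSO 4 and 11 without DMSO 1. With the block it was 33 without OICR623 1, 67 without OICR623 2, 83 without DMSO 2 and 67 without DMSO 3.

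HIF targets outside glycolysis rose as a list under OICR623 (mean 0.47 with the block, interval 0.30 to 0.63; mean 0.31 without it, adjusted p = 5.8e-33, and adjusted p = 0.52 with an estimated correlation). DDIT4 and EGLN3 were the 2 of 38 called without a block (9 adjusted over the list alone), and with it 11 rose and 1, BHLHE41 at -0.45, fell (20 and 1 adjusted over the list alone). The glycolysis list rose, with a mean of 0.20 with the block (interval 0.10 to 0.30) and 0.10 without it (median 0.02, adjusted p = 2.5e-08, and adjusted p = 0.99 with an estimated correlation). None of its members was called without a block and 4 rose with it (9 adjusted over the list alone), SLC2A3 at 0.91 (SE 0.14), SLC2A1 at 0.56 (SE 0.07), ENO2 at 0.51 (SE 0.09) and PDK1 at 0.35 (SE 0.07). The dioxygenase list passed with a block mean of 0.16 (interval 0.07 to 0.25; adjusted p = 0.033 without a block, where its mean was 0.00, and adjusted p = 0.99 with an estimated correlation). KDM3A, KDM7A, EGLN3 and P4HA1 rose with the block (5 adjusted over the list alone).

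Histones fell under OICR623, with a list mean of -0.64 with the block (interval -0.84 to -0.45) and -0.76 without it (adjusted p = 2.2e-44, and adjusted p = 0.32 with an estimated correlation). None of 30 was called without a block (12 lower adjusted over the list alone), and 13 fell with it (27 adjusted over the list alone), such as H3C8 at -0.92 (SE 0.09) and H4C2 at -0.99 (SE 0.12). G2/M genes fell as a list, with a mean of -0.14 with the block (interval -0.27 to 0.00) and -0.29 without it (adjusted p = 0.0059, and adjusted p = 0.99 with an estimated correlation). BUB1B, at -0.26, was the 1 member called lower with the block (4 lower and 1 higher adjusted over the list alone). The Wnt/beta-catenin list passed only with the level as a block (mean -0.15, interval -0.18 to -0.11; adjusted p = 1.6e-06, and adjusted p = 0.023 with an estimated correlation). In that fit 3 of its members fell (8 adjusted over the list alone), BAMBI at -0.84 (SE 0.07), FGF20 at -0.64 (SE 0.09) and PROX1 at -0.50 (SE 0.07), while AXIN2 at -0.24, LGR5 at -0.14, MYC at -0.27, NKD1 at -0.08 and CCND1 at 0.03 were not called. TFRC rose by 0.32 (SE 0.06, adjusted p = 0.045) with the block and stood at 0.02 without it. CDKN1A at 0.31, DDIT3 at -0.18 and SLC11A2 at -0.01 were not called. Cholesterol synthesis passed downward without a block (mean -0.26, adjusted p = 0.0081, and adjusted p = 0.99 with an estimated correlation) and not with it (mean -0.02, adjusted p = 0.47). The iron uptake list did not pass in either fit (block mean -0.01, interval -0.07 to 0.05). Lists that passed only with the block were also G1/S (mean 0.08, adjusted p = 0.0021), the unfolded protein response (0.07, adjusted p = 0.0055) and immediate early genes (0.08, adjusted p = 0.0029), all upward, and ribosome biogenesis (-0.08, adjusted p = 4.1e-05). At an estimated correlation none of these 4 passed. There were 6 lists past the set test without a block and 10 with it.

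**Figure D3:**
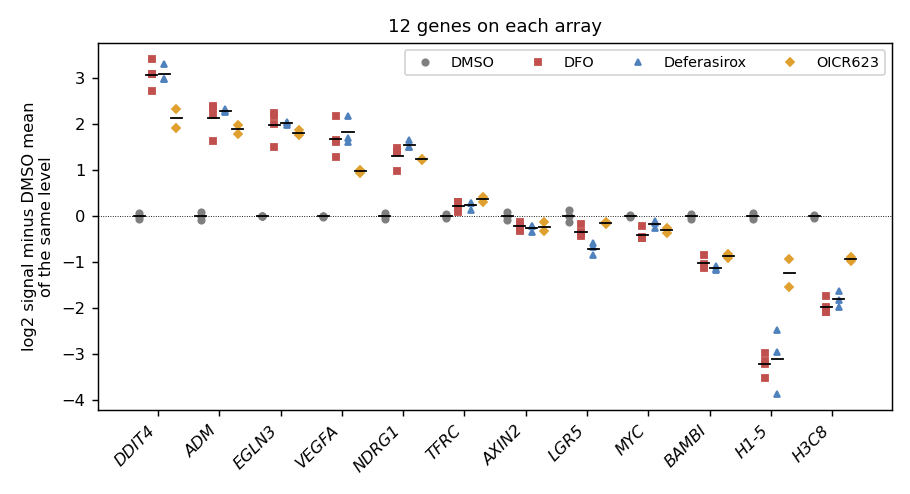
Log2 signal of 12 genes on each array, minus the mean of the DMSO arrays of the same level (y axis), with 1 symbol per array, 4 groups and short lines for group means. DDIT4, ADM, EGLN3, VEGFA and NDRG1 lie above and BAMBI, H1-5 and H3C8 below DMSO on each treated array, and for H1-5 the OICR623 arrays lie nearer to DMSO than the DFO arrays.

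The 3 compounds were then compared with each other, at doses that differed. Between OICR623 and DFO, histone genes were higher under OICR623 with the level as a block. H1-5 was higher by 1.86 (interval 1.30 to 2.42, adjusted p = 0.016), H2BC14 by 1.42 (0.99 to 1.85), H2AC21 by 1.37 (1.10 to 1.64), H3C11 by 1.34 (1.01 to 1.67) and H2BC7 by 1.34 (1.02 to 1.65). The histone list had a difference of 0.81 (interval 0.61 to 1.00), with 14 of 30 higher (28 adjusted over the list alone) and 0 lower. It passed without a block as well (mean 0.69, adjusted p = 1.5e-91, and adjusted p = 0.034 with an estimated correlation). DDIT4 was lower under OICR623 by 0.93, with a difference of -0.93 (-1.24 to -0.63), and so was GPR171 (-0.45). The median of all genes differed by -0.11 without a block. The HIF list differed by -0.20 with the block (interval -0.36 to -0.03) and -0.36 without it (adjusted p = 3.4e-17, and adjusted p = 0.99 with an estimated correlation). The G2/M list differed by 0.24 with the block (interval 0.11 to 0.37) and 0.09 without it (adjusted p = 7.9e-08, and adjusted p = 0.99 with an estimated correlation). In limma 0 genes were called without a block, with 60 at an unadjusted p under 0.05, and 31 with the level as a block, 29 higher and 2 lower. The blocked count was 15 without DFO 2, 17 without DFO 3, 16 without OICR623 1 and 8 without OICR623 2.

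Between OICR623 and Deferasirox, histone genes were again higher under OICR623 with the level as a block, among them H3C10 by 1.05 (interval 0.81 to 1.29, adjusted p = 0.0090), H1-2 by 1.02 (0.73 to 1.31) and H2AC21 by 0.98 (0.71 to 1.26). The histone list differed by 0.62 with the block (interval 0.42 to 0.82) and 0.72 without it (adjusted p = 2.9e-63, and adjusted p = 0.11 with an estimated correlation). The 5 genes that were lower under OICR623 were the clock gene PER2 at -0.53 (-0.66 to -0.41), JUN at -0.53 (-0.65 to -0.40), SLFN5 at -0.53, PCDHB5 at -0.53 and PAX8-AS1 at -0.40. The unfolded protein response list differed by -0.13 with the block (interval -0.20 to -0.05) and -0.05 without it (adjusted p = 0.0099, and adjusted p = 0.98 with an estimated correlation). In limma 0 genes were called without a block, with 47 at an unadjusted p under 0.05, and 16 with the level as a block, 11 higher and 5 lower. The blocked count was 1 without Deferasirox 1 and 0 without either OICR623 array.

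Between Deferasirox and DFO, NRP2 was lower under Deferasirox with the level as a block, at -0.73 (interval -0.89 to -0.57, adjusted p = 0.0064), as were DHRS3, of retinoid metabolism, at -0.60 (-0.74 to -0.47) and CHKA, a choline kinase gene, at -0.48 (-0.58 to -0.39). The 5 genes that were higher, IVNS1ABP, PAX8-AS1, PCDHB5, PER2 and SLFN5, overlapped between the groups on the deposited scale and were named after their values were seen. The unfolded protein response list was higher by 0.15 (interval 0.09 to 0.21) under Deferasirox with the block, although without a block its mean difference was 0.00 and that of all genes had a median of -0.16 (adjusted p = 1.2e-07, and adjusted p = 1.00 with an estimated correlation). The histone list passed in both fits, with a difference of 0.19 with the block (interval 0.02 to 0.36) and a mean of -0.03 without it (adjusted p = 1.2e-07, and adjusted p = 1.00 with an estimated correlation). With the block it had adjusted p = 1.6e-07, and adjusted p = 0.58 with an estimated correlation. None of its members was called in either fit, also adjusted over the list alone. In limma 0 genes were called without a block, with 44 at an unadjusted p under 0.05, and 8 with the level as a block, with 1847 at an unadjusted p under 0.05. Other settings called more, 93 with array weights and no block, and with the level as a block 107 with genes dimmer than the median gene left out and 116 with trend and robust moderation. Of the 8 calls, 0 were left without DFO 4, Deferasirox 1 or Deferasirox 3 and 2 without Deferasirox 2. Other splits of these arrays gave up to 6 lists without a block and 8 with it, against 3 and 7.

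Several genes fixed by name were not called between compounds by limma with the level as a block, although some intervals given here leave out 0. These are the intervals of LGR5 and MYC, and those of VEGFA for OICR623 minus DFO and OICR623 minus Deferasirox. For OICR623 minus DFO the difference was -0.27 (interval -0.55 to 0.01) for EGLN3, -0.66 (-0.98 to -0.34) for VEGFA, -0.11 (-0.32 to 0.10) for NDRG1 and 0.09 (-0.04 to 0.23) for TFRC. For OICR623 minus Deferasirox it was -0.23 (-0.52 to 0.05) for EGLN3, -0.74 (-1.07 to -0.41) for VEGFA and 0.53 (0.33 to 0.72) for LGR5, the last with an adjusted p of 0.063. For Deferasirox minus DFO it was -0.04 (-0.27 to 0.20) for EGLN3, 0.08 (-0.20 to 0.35) for VEGFA, -0.34 (-0.50 to -0.17) for LGR5 and 0.27 (0.14 to 0.40) for MYC.

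The 7 genes raised by OICR623 without a block, ARRDC3, DDIT4, ERRFI1, EGLN3, CHST15, HUNK and MOB3A, were raised by all 3 compounds, and 0 genes were lowered by all 3. The number shared was 1 without either OICR623 array, 4 without DMSO 2 and 11 without DMSO 1. In the blocked fit 30 genes were shared without OICR623 1, 56 without OICR623 2, 79 without DMSO 2 and 64 without DMSO 3. HUNK rose by 1.16 (SE 0.16) under DFO and 1.21 (SE 0.17) under Deferasirox, and MOB3A by 1.32 (SE 0.13) and 1.43 (SE 0.14). DFO and Deferasirox shared 16 of the genes that rose and 24 of those that fell, where independent lists would share 0.0196 and 0.0340. With the level as a block all 3 compounds shared 60 higher and 65 lower genes, where independent lists would share 0.0331 and 0.0596, and DFO and Deferasirox shared 263 higher genes, where independent lists would share 9.82, and 325 lower genes. Simulated unchanged groups against the same controls shared 0, which the threshold alone would give, so this value sets no level for the overlap. No gene was called in opposite directions by any pair of compounds in either fit.

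Across genes, which are not independent replicates, the changes under DFO and Deferasirox had a Pearson correlation of 0.750 without a block and 0.815 with the level as a block. Those under DFO and OICR623 had 0.555 and 0.728, and those under Deferasirox and OICR623 0.736 and 0.725. Unchanged groups that shared the DMSO arrays gave 0.462, 0.407 and 0.379 without a block and 0.446, 0.385 and 0.400 with it in simulations. Without a block the simulated noise was independent between arrays, although its size included the levels. Real arrays of 1 level share their shift, so these simulations set no fair level for the fit without a block. With the DMSO arrays split 2 and 2 so that no control was shared, the correlations were 0.243 (-0.0311 to 0.570), 0.0939 (-0.271 to 0.481) and 0.268 (0.0638 to 0.411), as the mean and range of 6 assignments. Each split gave DMSO 1, the only DMSO array of the high level, to 1 compound of the pair. The levels were thus not balanced between the control sets. These correlations therefore cannot tell the effect of shared controls from that of the levels. Within the middle level, with 1 DMSO array for each compound, the means of 2 assignments were 0.476, 0.388 and 0.378. The covariance of the changes minus that of the simulations was -0.00764, -0.0148 and -0.00534 without a block and 0.0175, 0.0116 and 0.0121 with it. Given the limit of the simulations without a block, the negative values do not show that the compounds covaried less than unchanged groups. Within the middle level, with separate controls, the covariance was 0.0169, 0.0114 and 0.0110. Without a block the correlation of DFO and OICR623 was 0.334 without DFO 3.

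**Figure D4:**
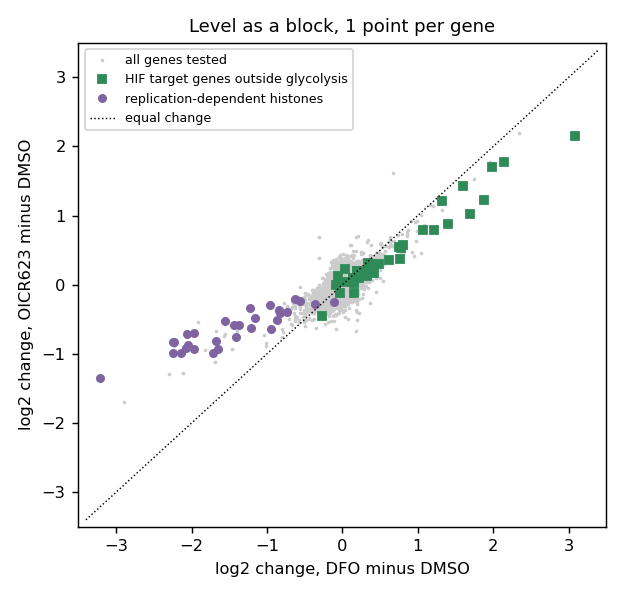
Log2 change against DMSO under DFO (x axis) and OICR623 (y axis) for each gene in the fit with the level as a block, with the 38 HIF targets as squares, the 30 histones as circles and a dotted line of equal change. Histones with the lowest values under DFO lie above the line, as H1-5 does at -3.21 and -1.35, and DDIT4 lies below it at 3.08 and 2.14.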

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

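The tests of the G1/S list, of the middle level, of the ratio of list changes and of exact values shared by arrays were chosen after the results had been seen. The splits of the arrays for lists with the level as a block were run after those without a block had been seen, the splits that keep the levels were counted after all other splits had been seen, and the scale of the test for single arrays was chosen after both scales had been counted.

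In groups of 4 arrays, a single array was held to stand apart when its gap to the nearest other array, divided by the range of the group, passed Dixon's critical value. Of 104 such tests, 10 did so on signals relative to the array median and 34 did so on the deposited scale; chance gives about 1 in 20. DMSO 1 stood apart for EGLN3 with a ratio of 0.846, at 2.69 above its array median against 2.36 to 2.41 in the other DMSO arrays. It also stood apart for H2AC20 (0.852), PDK1 (0.955), MOB3A (0.919), the HIF target list (0.891) and the ATF4 list (0.954). DFO 1 stood apart for ARRDC3 (0.852), CHST15 (0.870), H2AC20 (0.869) and LGR5 (0.961), where LGR5 lay 0.55 above the array median against -0.47 to -0.44 in the other DFO arrays. All 10 involved DMSO 1 or DFO 1, the only arrays of their groups in the high level. Whether they belong to single arrays or to the level thus cannot be told. The chance rate of 1 in 20 takes no account of levels.

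Among the 13163 transcript clusters without exactly 1 gene symbol, which the comparisons of genes did not use, 11 were called under DFO without a block (4 higher and 7 lower) and 8 under Deferasirox (2 higher and 6 lower). Under OICR623 0 were called by limma, and with the level as a block the counts were 99, 119 and 11.

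The lower signal of replication-dependent histones under DFO (mean -1.45) was set against explanations that would lower more than these genes. A poorer yield of all short transcripts without a poly(A) tail was argued against by 72 brighter RNA genes of that kind. Their median change was -0.0758 (SE of their mean 0.0197). With the level as a block 6 of these were called lower and 0 higher. They are small nuclear, nucleolar and similar RNAs and not histone messages. A poorer yield of histone messages alone was therefore not tested and stays open. A change of all histone genes alike was argued against by the 8 replication-independent histones, at a median of -0.0123 (SE of their mean 0.0339). With the level as a block 1 of these 8 was called lower and 0 higher. A general fall of G1/S transcripts was argued against by the mean of 0.216 of the G1/S list. As a hypothesis, the fall may be specific to the transcripts that cells remove when DNA replication stops. DNA synthesis was not measured, so whether replication had slowed stays open.

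Histones fell less under OICR623 than under DFO, by 0.81 as a list mean. The levels of the arrays were argued against as the cause by the difference within the middle level, 0.857 (SE 0.0632). A single scaling factor for the whole response was argued against by the ratio of OICR623 to DFO changes, which was 0.702 for the HIF list and 0.444 for the histone list, a difference of 0.258 (interval 0.0487 to 0.467). Each compound was used at 1 dose and OICR623 on 2 arrays, so a difference in dose and a difference in the compounds both stay open and were not tested.

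The 3 levels of the array medians did not follow the treatment groups. Arrays of 1 level shared a median of 77.5 exact values and arrays of different levels 0, which is consistent with normalization of the arrays in separate sets. Whether the sets also differed in the day of the experiment or of hybridization stays open, since the labels give neither. No biological explanation was tested.

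Other splits of the arrays into groups of the same sizes were fitted, 35 for each comparison with the real one included. For genes under DFO, 1 of the 35 splits, the real one, gave as many as the 45 without a block and the 847 with the level as a block, and the highest other split gave 0. If the replicate numbers pair these arrays, which the data do not settle, the real split compares with the 8 that part as many pairs. There the highest other also gave 0, and 8 splits are too few for a share under 0.05. For lists under DFO, 6 splits gave at least the 10 lists without a block, the highest other 13, so chance was not excluded. With the level as a block 1 of the 35 splits gave as many as 13, the highest other 11. The highest other of the 8 that part as many pairs was 10 without a block and 11 with it, and these 8 are again too few for a share under 0.05.

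For genes under Deferasirox, 1 of the 35 splits gave as many as 43 without a block (highest other 17) and 1 as many as 1074 with the level as a block (highest other 733). Arrays of different levels are not exchangeable, and 12 of the 35 splits keep the number of arrays of each level in each group, where the highest other also gave 17 and 733; 12 splits are too few for a share under 0.05. The split with 733 genes set DMSO 2, DMSO 3 and DMSO 4 against DMSO 1 and the Deferasirox arrays and so differed from the real one by DMSO 1 alone. For lists under Deferasirox 3 splits gave at least 12 without a block (highest other 14) and 7 splits at least 12 with the level as a block (highest other 15), so chance was not excluded. For Deferasirox against DFO all 35 splits gave at least the 0 genes called without a block (highest other 0), and 1 split as many as the 8 with the level as a block (highest other 1, and 0 among the 12 that keep the levels, again too few for a share under 0.05). For lists of that comparison 16 splits gave at least 3 without a block (highest other 6) and 3 splits at least 7 with it (highest other 8), so chance was not excluded. OICR623 had 2 arrays and was not put to other splits.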

How the results depend on the processing

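The level block, the middle level alone, the fit without the high level, the replicate block on the DFO and DMSO arrays alone and all alternatives of the level-blocked fit were chosen after the data had been seen. Comparisons with DMSO are named by the compound. The cause of a change was not tested unless it is given. Of the named genes called without a block, 865 values under an alternative kept direction and call and 66 lost the call; of those not called, 1173 stayed so, 66 gained a call and 2 reversed. For lists past the set test 812 values kept it and 91 lost it, and for the others 179 stayed and 72 gained it. These list values leave out the 2 other set tests, camera with an estimated correlation and fry. Under both of them most lists that passed without a block no longer did, as the counts below show. Both reversals were TFRC under Deferasirox, -0.01 without a block, at 0.26 with array weights and 0.23 with the level block.

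With the level block, genes called went to 847 under DFO, 1074 under Deferasirox, 135 under OICR623, 31 for OICR623 minus DFO, 16 for OICR623 minus Deferasirox, 8 for Deferasirox minus DFO and 125 for all 3 compounds. The lists went to 10 for OICR623 and 7 for Deferasirox minus DFO, and the correlation of DFO and OICR623 to 0.728. The residual spread fell when levels were removed, as the median SE went from 0.204 to 0.0555 under DFO. In the middle level alone there were 274, 326, 81, 29, 7 and, for all 3, 78 genes (Deferasirox minus DFO stayed at 0), lists of 10 for OICR623 and 6 for OICR623 minus DFO, and a correlation of 0.745 for DFO and OICR623. Without both arrays of the high level there were 198, 238, 41, 9, 2 and, for all 3, 41 genes, lists of 10 for OICR623 and 7 for Deferasirox minus DFO, and a correlation of 0.647 for Deferasirox and OICR623.

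Quantile normalization gave 161 genes under DFO, 185 under Deferasirox, 25 under OICR623, 14 for OICR623 minus DFO and 25 for all 3, with 6 lists for Deferasirox minus DFO. Centring arrays on their medians gave 154, 170, 19, 9 and 19 genes and 7 lists. Array weights gave 560, 845 and 172 genes against DMSO, 71 for OICR623 minus DFO, 82 for OICR623 minus Deferasirox and 93 for Deferasirox minus DFO, with 11 lists for OICR623 and 7 for OICR623 minus DFO. With only the groups compared, OICR623 had 1 gene.

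The replicate block gave 78 genes under DFO, 127 under Deferasirox, 13 lists for OICR623 minus Deferasirox and a correlation of 0.808 for Deferasirox and OICR623. On the 8 DFO and DMSO arrays alone it gave 619. It changed no call of a named gene over all 13 arrays, and with the 8 arrays alone 5 gained a call. Deviations of same-numbered arrays correlated at -0.06, 0.33 and -0.32 for Deferasirox and DMSO, and at 0.29 and -0.01 for OICR623 and DMSO. These deviations hold the levels too, so they do not settle whether the numbers pair these arrays. The numbers do not follow the levels here. Deferasirox 1 and OICR623 1 lie in the middle level, but DMSO 1 and DFO 1 in the high level. Deferasirox 3 lies in the low level, but DMSO 3 and DFO 3 in the middle level. The replicate block over all 13 arrays therefore joins arrays of different levels and does not remove the levels.

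With all transcript clusters, which also raises the number of tests, OICR623 had 4 genes and all 3 compounds 4, or 74 and 72 with the level block. The correlations became 0.634 for DFO and Deferasirox and 0.617 for Deferasirox and OICR623, and with the level block 0.661, 0.559 (DFO and OICR623) and 0.578. With genes dimmer than the median gene left out they became 0.848, 0.689 and 0.808, and 0.898, 0.859 and 0.845 with the level block. In that setting there were 9 lists for Deferasirox minus DFO, and level-block counts were 303 for OICR623, 270 for all 3, 107 for Deferasirox minus DFO and 103 for OICR623 minus Deferasirox. With trend and robust moderation the level-block counts were 336 for OICR623, 51 for OICR623 minus DFO, 109 for OICR623 minus Deferasirox and 116 for Deferasirox minus DFO.

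At an adjusted p under 0.01, a stricter threshold, 26 genes were called under Deferasirox, 4 under OICR623 and 4 by all 3. A log2 change of at least 1 left 57, 61, 18, 15, 2 and 0 of the level-block calls, in the order above, and 18 for all 3. With controls split 2 and 2 the correlations were 0.243, 0.0939 and 0.268 and the mean number of genes shared by all 3 was 3.5. These splits do not balance the levels between the control sets, so the correlations do not show the effect of shared controls alone. Within the middle level the correlations were 0.476, 0.388 and 0.378.

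With an estimated correlation, lists past the set test fell from 10 to 2 under DFO, 12 to 1 under Deferasirox, 6 to 0 under OICR623, 12 to 1 for OICR623 minus DFO, 8 to 0 for OICR623 minus Deferasirox and 3 to 0 for Deferasirox minus DFO. With the level block they fell to 4, 3, 2, 1, 1 and 0. With fry 1, 1, 0, 0, 0 and 0 lists passed without a block, and 12, 14, 6, 3, 4 and 2 with the level block.

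Leaving out each array in turn, counts without a block ranged from 36 (DFO 2) to 81 (DMSO 1) under DFO, 22 (Deferasirox 3) to 73 (DMSO 1) under Deferasirox and 1 (OICR623 1) to 11 (DMSO 1) under OICR623 and for all 3. With the level block they ranged from 494 to 769, 546 to 986, 33 to 173, 8 to 29 (OICR623 minus DFO), 0 to 21 (OICR623 minus Deferasirox), 0 to 10 (Deferasirox minus DFO) and 30 to 162 (all 3). Fewer arrays also lower the degrees of freedom, and a lone OICR623 array is assumed to vary like the other groups. Lists ranged from 7 to 12 for OICR623 minus DFO and 1 to 7 for Deferasirox minus DFO, or 4 to 7 with the level block. Correlations ranged from 0.599 to 0.867 (DFO and Deferasirox), 0.334 to 0.745 (DFO and OICR623) and 0.638 to 0.813 (Deferasirox and OICR623), and with the level block from 0.769 to 0.826, 0.604 to 0.753 and 0.615 to 0.746. No signal could be set against background, so a lower limit of detection is not given.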

Other observations

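Apart from FGF20 and the histone genes at the end, the genes in this part lie outside the naming rule. They were chosen after their values were seen, and none of them was called without a block. All values are from the fit with the level as a block unless the other fit is named. No list of growth factors was fixed or tested, and FGF20, a growth factor gene that the rule did name, fell under all 3 compounds. TGFA, a ligand of the EGF receptor, rose by 1.04 (SE 0.06) under DFO, 1.24 (SE 0.07) under Deferasirox and 1.01 (SE 0.08) under OICR623. PDGFA, a platelet-derived growth factor gene, rose by 0.63 (SE 0.05), 0.76 (SE 0.06) and 0.57 (SE 0.07), and the cytokine gene LIF by 0.54 (SE 0.06), 0.58 (SE 0.06) and 0.56 (SE 0.07). ITGA5, which encodes a subunit of the fibronectin receptor, rose by 0.84 (SE 0.05), 0.94 (SE 0.06) and 0.55 (SE 0.07). SOX2, a stem cell transcription factor gene, changed by -0.60 (SE 0.06), -0.60 (SE 0.06) and -0.47 (SE 0.08), and CDX2, an intestinal transcription factor gene, by -0.49 (SE 0.08), -0.77 (SE 0.09) and -0.44 (SE 0.11), the last not called.

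TXNIP, which restrains glucose uptake, changed by -0.82 (SE 0.09) under DFO, -0.60 (SE 0.10) under Deferasirox and -0.44 (SE 0.12) under OICR623, the last not called. ARRDC4 changed by -0.48 (SE 0.07), -0.69 (SE 0.08) and -0.51 (SE 0.10), all called. FBXL5, an iron-binding subunit of a ubiquitin ligase that acts on the iron regulatory protein IREB2, changed by -0.58 (SE 0.05), -0.50 (SE 0.06) and -0.52 (SE 0.07), all called. ALAS1, the first enzyme of heme synthesis, rose by 0.30 (SE 0.05) under DFO and 0.33 (SE 0.06) under Deferasirox, and stood at 0.36 (SE 0.07) under OICR623, not called. Of the mitotic genes outside the fixed lists, KIF18A changed by -0.88 (SE 0.06), -0.75 (SE 0.07) and -0.38 (SE 0.08, not called), and BORA by -0.88 (SE 0.07), -0.81 (SE 0.08) and -0.50 (SE 0.09).

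Histone genes of the same clusters that the fixed list did not hold numbered 26. Their median change was -1.39 under DFO (20 called lower), -1.17 under Deferasirox (19) and -0.63 under OICR623 (14) with the level as a block. Without a block 10 of them were called lower under DFO, 10 under Deferasirox and 0 under OICR623. Some of them, such as H3C12 and H2AC15, had been named above by the rule.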
